A study of Mus musculus with 6 samples.

How the data were processed

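Total RNA from 3 mock-treated and 3 LPS and IFN-γ treated samples of mouse bone-marrow-derived macrophages was labelled and hybridised to Illumina BeadChips, per the labels' protocols. BeadStudio is named in the submitters' processing notes, and its version and the genome build of the probes are not given in the sources used here. The deposited value table holds a linear intensity per probe and array, and its columns carry the samples' own identifiers. Its values were unnormalized when tested: the sorted columns differed by up to 1.03 log2 units, the lowest value left out. A second deposited table, although named as unnormalized, held columns whose sorted values differed by at most 0.0151 log2 units, as after quantile normalization, and its 6 signal columns are named by chip position, which no label ties to a sample. Those 6 columns were not used, and only its probe annotation was. The design had assumed a detection p per probe. None tied to a sample was used here, and detection was computed from the intensities instead.

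Background and detection were set with 1302 probes for olfactory receptors, genes expressed mainly in olfactory neurons, as stand-ins for negative control probes. A probe was detected on an array when the share of these probes at or above its unnormalized intensity was under 0.01. In limma 3.58.1 under R 4.3.3, intensities were background corrected by normexp with the stand-in controls (the neqc method), with an offset of 16, quantile normalized and put on the log2 scale. Probes detected on at least 3 of the 6 arrays were tested, 15634 in all, with the olfactory receptor probes left out. Fold changes of dim genes are understated on this scale because of the offset. Each gene was represented by its passing probe with the highest mean over all arrays, giving 11040 genes. Of these genes 3253 had over 1 passing probe, and 19 had probes called in opposite directions, among them Bcl2l11 and Npc1. Where a gene was above background on no array of 1 group, its fold is a bound: the mean of the other group against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

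Probe names were updated through a table of RefSeq genes (GRCm38.p6), used for names only: 29168 of 45281 probes were named by gene identifier and 2860 by accession, 2296 had a symbol listed there, and 10957 kept the symbol of the deposited annotation. No coordinates are given, since no build was named for them.

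The groups were compared with a linear model (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all passing probes, threshold 0.05). The 24 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and camera with a correlation estimated from the residuals and fry were alternatives. Camera compares a list with the other genes, and fry asks whether its genes move on balance in 1 direction, or change in either. With an estimated correlation, camera also rests on the few residual degrees of freedom of the arrays. Leaving out an array or adding a block leaves fewer of them. The design, the lists, 9 lists of markers of other cell types, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest called rises and falls among genes detected on all 6 arrays with separated groups, the 10 brightest called genes detected on all arrays of 1 group and none of the other in each direction, from each list up to 4 called genes in its main direction and up to 2 against it, and 15 genes always, among them Nos2, Tnf, Il6, Il12b, Il1b, Cxcl10, Irf1, Ciita, Arg1, Mrc1, Tlr4, Ifngr1, Gapdh and Actb. The text gives some of the genes the rule took from each list, and a few are not reported here. Genes named among the cell type markers, the other probes of Clspn and the members Ccr3, Cx3cr1, Tlr2, Tirap, Irak1, Gpi1, Lpl, Csf2ra, Dnajb9, Pdia4 and Ifit3, named to complete small counts, stand outside it and were chosen after their values were seen.

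On simulated data with 200 seeded genes of known fold for the comparison of LPS and IFN-γ with mock, at 14949 genes tested and a spread of 0.2 log2 units, 46% of 1.5-fold, 96% of 2-fold, 100% of 4-fold and 100% of 8-fold changes were recovered, and 4 unchanged genes were called. Median estimated folds were 1.45, 1.80, 3.54 and 7.14. These rates hold for the simulated spread only. In the data many genes spread more widely. Mock replicate 3 lay over 1 log2 unit above the mean of mock replicates 1 and 2 for 1274 genes and below it for 1746. Recovery and false calls at such a spread were not simulated. Alternatives changed the background correction, the scaling, the detection filter, the offset, the probe rule, the moderation of variances, the test, array weights, a block for the replicate number and the arrays included. Alternatives added after the data were seen were normexp without controls (with an offset of 50), vomeronasal receptor probes as controls, scaling to the median of passing probes and removal of each array's trend with the probe's start in its transcript. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.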

Results

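Macrophages grown in culture from the bone marrow of C57/BL6 mice aged 8 weeks were compared after 8 h with lipopolysaccharide (LPS, a bacterial cell wall component that Toll-like receptor 4 recognises) at 10 ng/ml together with interferon-γ (IFN-γ, a cytokine of lymphocytes) at 20 ng/ml, and after mock treatment. The question the design put was how transcript levels differ between these states. Total RNA of 6 samples, 3 per group and called biological replicates in the labels, was measured on Illumina BeadChips with 45281 probes. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, their number limits the precision.

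The unnormalized median intensity was 45.6, 44.9 and 44.8 on mock arrays 1, 2 and 3 and 44.6, 41.0 and 40.0 on stimulated arrays 1, 2 and 3. Probes above background numbered 15828, 15480 and 16856 on the mock arrays and 13396, 13962 and 13508 on the stimulated arrays. Over the 15634 probes that passed the filter, the stimulated arrays correlated with each other at r = 0.987 to 0.993 and mock replicate 1 with mock replicate 2 at r = 0.994 (across probes, which are not independent replicates). Mock replicate 3 correlated with the other mock arrays at only 0.915 to 0.916. It lay over 1 log2 unit above the mean of mock replicates 1 and 2 for 1274 genes and below it for 1746, whereas mock replicates 1 and 2 lay that far apart for 18 genes. This array was kept. Its median deviation is given below beside the gene groups it moved with.

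Stimulated macrophages gained transcripts of many inflammatory cytokines, chemokines, interferon-stimulated genes and genes of antigen presentation, and lost transcripts of many cell cycle genes. Among genes detected on all 6 arrays, the largest rises were those of Serpina3g, a serine protease inhibitor, at 241-fold, AA467197 at 137-fold, Cd40, a costimulatory receptor, at 121-fold, and Il1b, the cytokine interleukin 1β, at 112-fold. In log2 units these were 7.91, 7.10, 6.92 and 6.81. Against mock replicates 1 and 2 alone they were 7.36, 6.53, 6.45 and 6.38, and Socs3, described below, then ranked above AA467197 with 6.66. Cxcl9, a chemokine induced by IFN-γ, was above background on no mock array and reached 14.91 ± 0.14 (SD, n = 3) on the stimulated arrays in normalized log2 intensity, at least 932-fold higher. Nos2, the inducible nitric oxide synthase, was likewise below background in mock cells and at least 145-fold higher after stimulation. The largest falls among genes detected on all arrays were those of St6gal1, a sialyltransferase, at 37.5-fold, Sesn1, a sestrin, at 34.3-fold, LOC100048845 at 23.3-fold and Pparg, a lipid-sensing nuclear receptor, at 21.9-fold. Their size and order depend on mock replicate 3. It lay above mock replicates 1 and 2 for St6gal1 (12.48 against 10.95 and 10.60), Sesn1 (13.61 against 12.54 and 12.42) and LOC100048845 (13.21 against 11.49 and 11.48). For Pparg it lay slightly below them (10.33 against 10.63 and 10.52).

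Of 11040 genes tested, 1792 were higher and 2487 lower in stimulated cells (limma, Benjamini-Hochberg adjusted p under 0.05), and 1276 were at least 2-fold higher and 1655 at least 2-fold lower. The split depended on the scaling and on the mock arrays included. The median log2 fold change of all genes was -0.11 with quantile normalization, -0.60 with arrays scaled to the median of all probes, where 1112 genes were higher and 4814 lower, and 0.12 with arrays scaled to the median of passing probes, where 2523 were higher and 1934 lower. Without mock replicate 3, 2749 genes were higher and 3410 lower, with 1783 and 1825 of the genes called with all arrays among them. Without mock replicate 1 or 2, 1456 or 1465 genes were higher and 1400 or 1475 lower, so falls no longer clearly outnumbered rises. Without stimulated replicate 1, 2 or 3, 1089, 1082 or 1131 were higher and 1619, 1566 or 1654 lower. Part of these drops was set by the filter, which still asked for detection on 3 arrays. Probes detected on the mock arrays only could not pass once a mock array was left out. These include the probes of 658 called genes, described below. The same held for 203 called genes detected on the stimulated arrays only, once a stimulated array was left out. The smaller excess of falls without mock replicate 1 or 2 is therefore partly built in. The filter left 9990, 10022 or 9974 genes to test without mock replicate 1, 2 or 3, and 10769, 10707 or 10763 without stimulated replicate 1, 2 or 3.

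**Figure D1:**
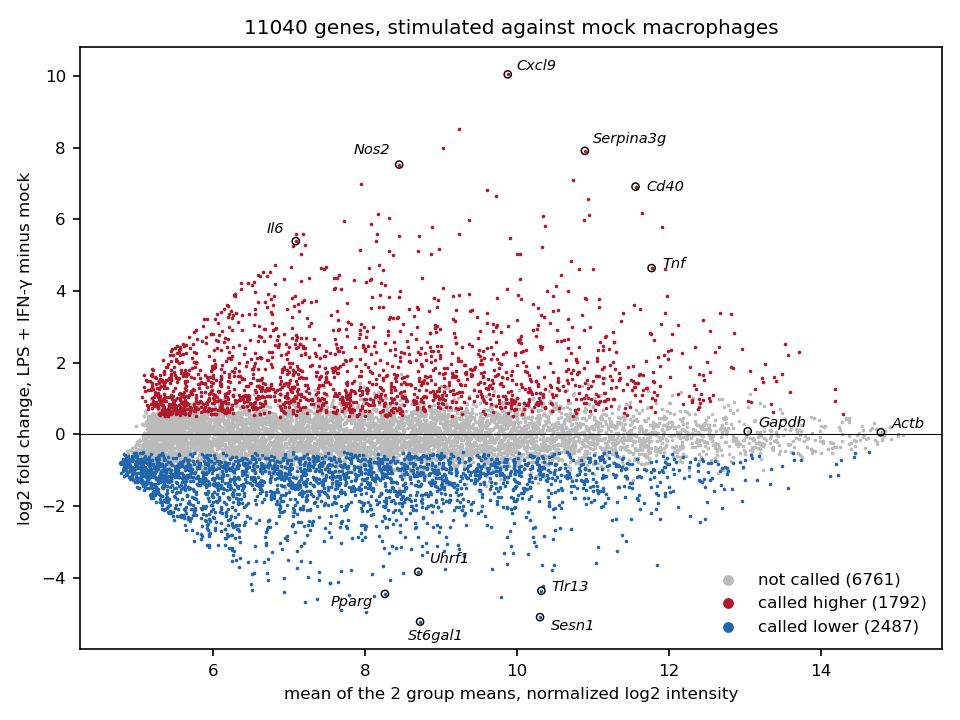
Log2 fold change (LPS and IFN-γ minus mock) of each of the 11040 genes against the mean of the group means in normalized log2 intensity, with 1792 genes called higher in red, 2487 called lower in blue and the rest in grey. Cxcl9 has the highest fitted log2 fold change of the labelled genes, 10.05, and St6gal1 the lowest, -5.23.

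At least 4-fold higher were 528 genes and at least 4-fold lower 400. Other large rises among genes detected on all arrays were those of Socs3, a feedback inhibitor of cytokine signalling, with a log2 fold change of 6.66 ± 0.16 (SE), the early activation antigen Cd69 with 6.57 ± 0.30, the chemokine Ccl5 with 6.19 ± 0.81, the acute-phase protein Saa3 with 6.13 ± 0.81, the interferon-inducible Ifi205 with 6.09 ± 0.45 and Cxcl10 with 5.99 ± 0.70. Leaving out mock replicate 3 gave 5.28 for Ccl5, 5.25 for Saa3 and 5.26 for Cxcl10, and leaving out mock replicate 2 gave 7.01 for Ccl5 and 6.86 for Saa3. Serpina3g and Ifi205 have close paralogs whose transcripts their probes could also bind. Detected on all stimulated arrays and on no mock array were 203 called genes. The brightest after Cxcl9 and Nos2 were the cytokine subunit Il27 (at least 84.9-fold higher), the kinase Lck (at least 50.3-fold), Tarm1 (at least 30.5-fold), Slamf1 (at least 28.7-fold), endothelin 1, Edn1 (at least 28.3-fold), Il6 (at least 26.9-fold), the cholesterol hydroxylase Ch25h (at least 24.9-fold) and LOC100047856 (at least 24.8-fold).

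The lowest normalized log2 intensity among detected probes was 5.07, 5.12 and 4.94 on mock arrays 1, 2 and 3. On stimulated arrays 1, 2 and 3 it was higher, at 5.53, 5.40 and 5.50. A dim gene could therefore lose detection after stimulation with only a small fall. Detected on all mock arrays and on no stimulated array were 658 called genes, a count that this difference may raise against the 203 above. The brightest were 3830612M24 (at least 16.9-fold lower), Gpr155 (at least 12.7-fold), Fignl1 (mock mean 8.94 in normalized log2 intensity), the topoisomerase Top2a (at least 10.9-fold), Gcnt1 (at least 9.75-fold), the cytokinesis protein Anln (at least 9.28-fold), the condensin subunit Ncaph (at least 9.05-fold), Rasgrp3 (at least 8.69-fold), the replication checkpoint protein Clspn (at least 8.03-fold) and Nlrc3 (at least 7.98-fold). Of 3 other passing probes of Clspn, 2 were called lower, with log2 fold changes of -3.69 and -1.44. The third, used when detection was required on all 6 arrays, gave -0.30 and no call, and the probe used on leaving out any mock array gave none either (adjusted p up to 0.433). Among genes detected on all arrays, LOC100048845 fell by 4.54 on the log2 scale, the nucleic acid sensor Tlr13 fell by 4.37, the transporter Slc46a3 fell by 4.22, Fam214a fell by 4.12, Cdca7 fell by 4.07, 2810410A03Rik fell by 3.90 and the kinase Aatk fell by 3.86. Other passing probes of some genes gave smaller log2 fold changes. Among these were 2.06 for Nos2, 3.96 for Slamf1, -2.58 for Pparg, -0.92 for Top2a, 4.66 for Acod1, -2.93 for Gpr155, -2.80 for Ncaph and -3.56 for LOC100048845. Per gene the smallest were 3.03 for Cd40, 3.99 for Ifi205, 3.26 for Slc7a2, 3.19 for Gbp5, 1.71 for Hspa1a, 3.10 for Ccnd2 and -1.73 for Mcm6. Some gave larger ones, up to 8.09 for Cd40, 6.42 for Oasl1 and 6.31 for Traf1, and 3.32 to 3.99 for the other 4 probes of Irf1.

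Inflammatory cytokines rose nearly as a whole. Of 20 measured, 19 rose and 1 fell, with the same counts adjusted over the list alone, and the list ranked above other genes (camera adjusted p = 2.30e-14; adjusted p = 0.0644 with an estimated correlation). Il1a, detected on 2 mock arrays, rose 65.4-fold, and Tnf, the tumour necrosis factor, rose by 4.64 ± 0.37 (SE) on the log2 scale, from 9.45 ± 0.78 to 14.09 ± 0.12 (SD, n = 3, normalized log2 intensity). Il12b, a subunit of interleukins 12 and 23, was below background in mock cells and at least 2.09-fold higher after stimulation, at 6.11 ± 0.19. Tgfb1 was the member that fell, by 0.54 ± 0.17 (SE) on the log2 scale, with adjusted p = 0.0378, a call lost on leaving out any array other than mock replicate 3 (adjusted p up to 0.148) and under other settings (up to 0.668).

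Chemokines rose in 9 of 16 measured genes, fell in 1 and did not pass in 6, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.32e-05; adjusted p = 0.401 with an estimated correlation). Besides Cxcl9, Ccl5 and Cxcl10, Ccl24 was at least 15.8-fold higher. Cxcl14 was called lower and was above background on no stimulated array. Its mock mean of 5.19 already lay below the lowest detected value of each stimulated array, 5.40 to 5.53, so no fold could be bounded. Its call was lost without stimulated replicate 2 (adjusted p = 0.0553), with an offset of 50 (0.0553) and with scaling to the median of passing probes (0.511). The chemokines of mock replicate 3 had a median deviation of -1.24 log2 units from the other mock arrays. Receptors for chemokines and other attractants went both ways, with 6 higher, 4 lower and 3 not called of 13, the same adjusted over the list alone (camera adjusted p = 0.205). The formyl peptide receptor Fpr2 rose 62.9-fold and Ccrl2 33.0-fold, while Cxcr4 fell by 2.00 and the complement receptor C5ar1 fell by 1.46 on the log2 scale, the others called lower being Ccr3 and Cx3cr1. Without mock replicate 3 this list passed upward (camera adjusted p = 0.0464; adjusted p = 0.250 with an estimated correlation), and with arrays scaled to the median of all probes its median turned from 0.26 to -0.36, above the -0.60 of all genes. It passed upward there, relative to other genes (camera adjusted p = 0.0336; adjusted p = 0.164 with an estimated correlation).

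Antiviral interferon-stimulated genes rose in 33 of 34 measured members and 1, Ifit3, did not pass, with the same counts adjusted over the list alone (camera adjusted p = 2.90e-16; adjusted p = 0.123 with an estimated correlation). The oligoadenylate synthetase-like gene Oasl1 rose 56.3-fold, the ubiquitin-like Isg15 28.6-fold and the exonuclease Isg20, detected on 1 mock array, 24.9-fold. The log2 fold change of Isg15, 4.84, was 3.97 without mock replicate 3 and 5.56 without mock replicate 2. In mock replicate 3 the list lay at a median of -0.52 from the other mock arrays. All 12 measured interferon-inducible GTPases, proteins that act on vacuoles of intracellular pathogens, rose, adjusted over the list alone as well (camera adjusted p = 2.32e-10; adjusted p = 0.111 with an estimated correlation). Gbp5, detected on 1 mock array, rose 71.2-fold, Gbp10 25.6-fold and Gbp3 10.5-fold, and Tgtp1 was at least 9.60-fold higher. Members of these families resemble each other closely, so single members are uncertain.

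For MHC class I, 15 of 19 rose and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 1.15e-06; adjusted p = 0.262 with an estimated correlation), and examples were the peptide transporter Tap1 at 8.35-fold, Tap2 at 5.98-fold and the regulator Nlrc5 at 6.70-fold. For MHC class II, 8 of 11 rose and 3 did not pass, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00290; adjusted p = 0.329 with an estimated correlation). Ciita, the transactivator of class II genes, rose 16.8-fold and H2-DMa 5.25-fold. Mock replicate 3 deviated by a median of -0.62 for the class I list and -1.18 for the class II list. Costimulatory and checkpoint molecules rose in 12 of 15 genes, fell in 1 and did not pass in 2, with 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 5.43e-07). Slamf8 rose 17.6-fold, and Havcr2, which encodes the receptor TIM-3, fell by 3.25 ± 0.44 (SE) on the log2 scale and was detected on 1 stimulated array.

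In the NF-kB pathway 21 of 24 genes rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 3.22e-12), with Traf1 at 36.3-fold and the inhibitor Nfkbie at 11.7-fold, and the inhibitor Nfkbia at a log2 fold change of 3.80. In JAK-STAT signalling 16 of 24 rose, 2 fell and 6 did not pass, with 17 and 3 adjusted over the list alone (camera adjusted p = 1.25e-05; adjusted p = 0.329 with an estimated correlation). The kinase Jak2 rose 11.1-fold (log2 fold change 3.47, and 4.09 without mock replicate 3), whereas Il6ra fell by 2.57 and Ifngr1, a chain of the IFN-γ receptor, fell by 2.18 ± 0.19 (SE) on the log2 scale. Mock replicate 3 deviated by a median of 0.45 for this list. Of 26 inducible transcription factors 14 rose, 8 fell and 4 did not pass, with 15 and 9 adjusted over the list alone (camera adjusted p = 0.0253; adjusted p = 0.329 with an estimated correlation). Batf rose 34.9-fold, Batf2 32.6-fold, Irf7 13.8-fold and Irf1 7.06-fold, while the immediate-early genes Egr1 fell by 3.06 and Fos fell by 1.98 on the log2 scale. This list missed the threshold without mock replicate 1 (camera adjusted p = 0.0611), without mock replicate 2 (0.0505) and with scaling to the median of passing probes (0.0622), and mock replicate 3 deviated by a median of -0.38 for it.

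Toll-like receptors and adaptors went both ways, with 10 higher, 5 lower and 9 not called of 24, and 11 and 6 adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.433 with an estimated correlation). The adaptor kinase Ripk2 rose 7.36-fold and the sensor Nod1 8.41-fold. Tlr4, the LPS receptor, fell by 1.69 ± 0.41 (SE) on the log2 scale with adjusted p = 0.0145, a call lost without stimulated replicate 1 or 3 (adjusted p up to 0.0614) and under other settings (up to 0.0776). The others called lower were Tlr13, Tlr2, Tirap and Irak1. The list's call was lost on leaving out mock replicate 1 (camera adjusted p = 0.151), mock replicate 2 (0.157), stimulated replicate 1 (0.0710) or stimulated replicate 3 (0.0565), with detection on all 6 arrays (0.110) and with scaling to the median of passing probes (0.0622), and mock replicate 3 deviated by a median of 0.51 for it.

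**Figure D2:**
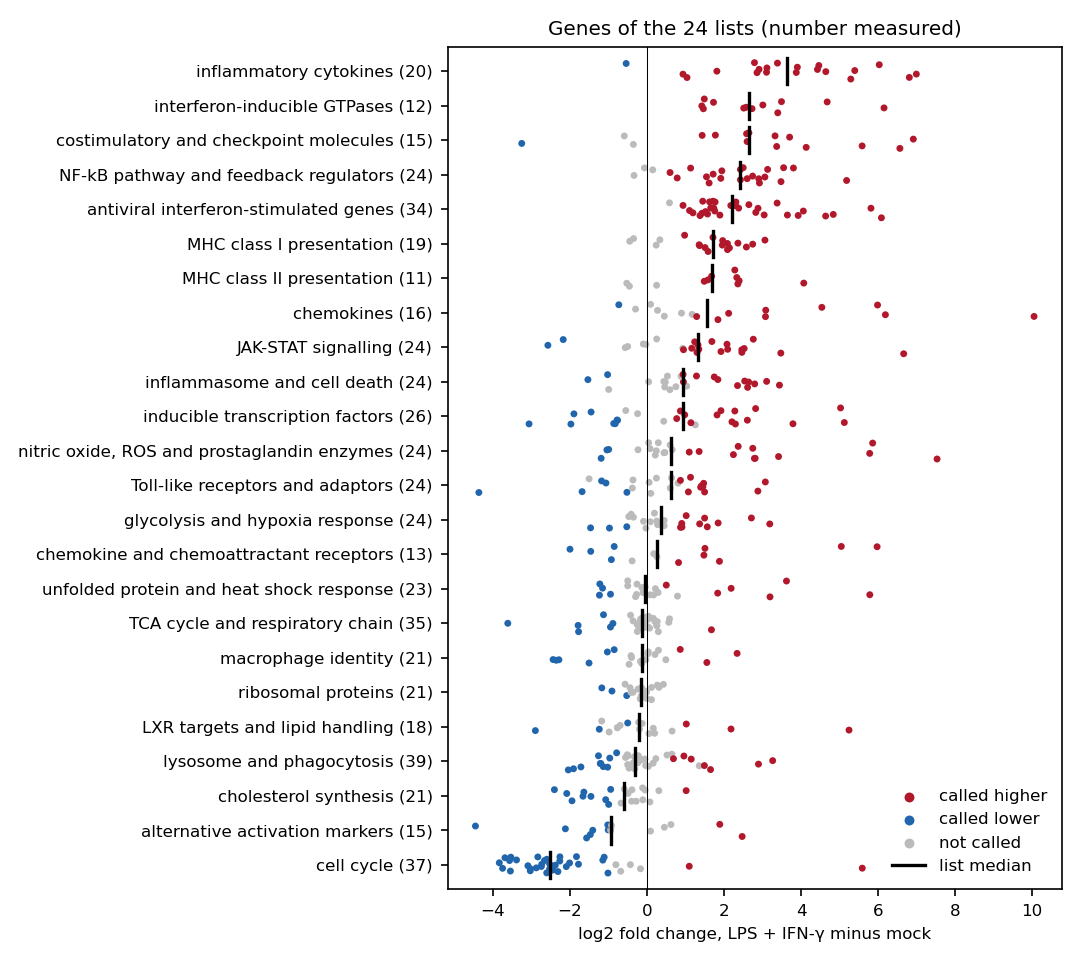
Log2 fold change (LPS and IFN-γ minus mock, horizontal axis) of each measured gene of the 24 lists, with called rises in red, called falls in blue, uncalled genes in grey and each list's median as a black bar. List medians run from -2.53 for the cell cycle to 3.63 for inflammatory cytokines.

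Enzymes of nitric oxide, oxidant and prostaglandin synthesis rose in 11 of 24 genes, fell in 3 and did not pass in 10, with 12 and 3 adjusted over the list alone (camera adjusted p = 4.22e-05; adjusted p = 0.0742 with an estimated correlation). Slc7a2, an arginine transporter, rose by 5.86 ± 0.20 (SE) on the log2 scale, Acod1, which makes itaconate, rose 55.0-fold, and the cyclooxygenase Ptgs2 was at least 6.82-fold higher, while Ptgs1 was at least 1.49-fold lower and Alox5ap was also called lower. This call was lost without mock replicate 1 or 2 or stimulated replicate 1 or 2 (adjusted p up to 0.0847) and under other settings (up to 0.611). Without mock replicate 3, 12 of 21 rose and 1 fell. Markers of alternative activation fell in 7 of 15 genes, rose in 2 and did not pass in 6, with 10 lower and 2 higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.139). With no filter it passed downward (camera adjusted p = 0.0279; adjusted p = 0.228 with an estimated correlation), with a median of -0.32 in place of -0.94. Stab1 fell by 2.12 and Clec10a fell by 1.57 on the log2 scale, while Ppargc1b rose 5.54-fold and Tgm2 3.71-fold. The mannose receptor Mrc1 fell by 1.01 ± 0.27 (SE) on the log2 scale with adjusted p = 0.0229, a call lost on leaving out any stimulated array (adjusted p up to 0.0942) and under other settings (up to 0.280). Arg1, an arginase, was above background on 0 arrays, with unnormalized intensities of 43.7 ± 2.32 in mock and 43.3 ± 6.34 in stimulated cells (SD, n = 3). Inflammasome and cell death genes rose in 12 of 24, fell in 2 and did not pass in 10, with 16 and 2 adjusted over the list alone (camera adjusted p = 1.17e-05). The death receptor Fas rose 10.8-fold and Casp4 8.61-fold, and the kinase Ripk1 fell by 1.02 on the log2 scale. Without mock replicate 3, 19 of these genes rose and 3 fell. The other gene called lower was Bcl2l11, whose other probes had log2 fold changes of 1.36, -1.03 and 0.27. It was not called with the mean of its probes (adjusted p = 0.398, the highest of its alternatives).

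In glycolysis and the hypoxia response 10 of 24 genes rose, 3 fell and 11 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.238 with an estimated correlation). The list's call was lost without mock replicate 2 (0.0505). The hexose transporter Slc2a6 rose 9.11-fold and the phosphofructokinase Pfkp 6.55-fold, while Pfkfb4 fell by 1.47 on the log2 scale and Pdk1 and Gpi1 were also called lower. Pdk1 was not called without mock replicate 2 or any stimulated array (adjusted p up to 0.116, the highest of its alternatives). In the TCA cycle and respiratory chain 6 of 35 fell, 1 rose and 28 did not pass, the same adjusted over the list alone (camera adjusted p = 0.472), and its median of -0.13 turned to 0.26 with scaling to the median of passing probes and to 0.061 without mock replicate 2. The cytosolic isocitrate dehydrogenase Idh1 fell by 3.61 and Idh2 fell by 1.78 on the log2 scale, and cytochrome c, Cycs, was the member called higher. Its call was lost on leaving out any stimulated array (adjusted p up to 0.0913) and under other settings (up to 0.109). Mock replicate 3 deviated by a median of -0.55 for this list, and without it 17 genes fell (camera adjusted p = 0.0159; adjusted p = 0.250 with an estimated correlation). Cholesterol synthesis fell in 9 of 21 genes, rose in 1 and did not pass in 11, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.329 with an estimated correlation). The squalene epoxidase Sqle fell by 2.40 on the log2 scale, and mock replicate 3 deviated by a median of 0.54. Of 18 LXR targets and lipid genes 3 rose, 3 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.856), and the median of -0.20 turned to 0.20 with scaling to the median of passing probes. Nr1h3, Mylip and Ch25h were called higher, and Lpl, Plin2 and the elongase Elovl6, at least 4.42-fold, lower. The log2 fold change of Nr1h3, 2.18, was 1.59 without mock replicate 3. Its call was lost without stimulated replicate 1 or 2 (adjusted p up to 0.0667, and 0.0851 under other settings). That of Mylip was lost without mock replicate 1 or 2 or stimulated replicate 3 (up to 0.0692, and 0.106 under other settings). Without mock replicate 3, 4 of 17 rose and 5 fell.

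Cell cycle genes fell in 31 of 37, rose in 2 and did not pass in 4, with the same counts adjusted over the list alone (camera adjusted p = 1.03e-11). The median log2 fold change was -2.53, and -2.14 with the 10 members that had only a bound placed at it. Uhrf1 fell by 3.84 ± 0.20, the replicative helicase subunit Mcm6 fell by 3.75 ± 0.36, Mcm2, detected on 2 stimulated arrays, fell by 3.57 ± 0.19, and the spindle protein Prc1 fell by 3.69 ± 0.27 on the log2 scale (SE). The members that rose were the cyclins Ccnd2, 48.2-fold, and Ccne1, 2.14-fold, the latter not called with arrays scaled to the median of all probes (adjusted p = 0.133, the highest of its alternatives).

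Lysosome and phagocytosis genes went both ways, with 7 higher, 10 lower and 22 not called of 39, and 8 and 10 adjusted over the list alone (camera adjusted p = 0.629), and the median of -0.32 turned to 0.47 with scaling to the median of passing probes. The lipase Lipa fell by 2.04 and the ligand Gas6 fell by 1.91 on the log2 scale, while the scavenger receptor Marco rose 9.60-fold and the Fc receptor Fcgr4 7.44-fold (log2 fold change 2.89, and 2.27 without mock replicate 3). Among 21 macrophage identity genes 3 rose, 6 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.472), and the median of -0.14 turned to 0.47 with that scaling. Without mock replicate 3, 5 rose and 6 fell. Csf1r, the receptor for macrophage colony-stimulating factor, fell by 2.44 ± 0.33 (SE) on the log2 scale, and Csf2rb rose 5.06-fold, Spi1 and Csf2ra also being called higher. Of 21 ribosomal protein genes 3 fell, 0 rose and 18 did not pass, with 1 lower adjusted over the list alone (camera adjusted p = 0.566), and the median of -0.14 turned to 0.58 with that scaling and to 0.057 and 0.078 without mock replicate 1 and 2. Rpl22 fell by 1.17, Rpl4 fell by 0.91 and Rpl3 fell by 0.53 on the log2 scale, and the calls of Rpl4 and Rpl3 were each lost on leaving out any array other than mock replicate 3 (adjusted p up to 0.109 and 0.167). Mock replicate 3 deviated by a median of -1.20 for this list, and without it 16 genes fell (camera adjusted p = 0.00108; adjusted p = 0.282 with an estimated correlation). Of 23 genes of the unfolded protein and heat shock responses 6 rose, 4 fell and 13 did not pass, with 6 and 6 adjusted over the list alone (camera adjusted p = 0.412), and the list's median of -0.049 and mean of 0.52 differed in sign. The median turned positive with scaling to the median of passing probes (0.27) and on leaving out any array other than stimulated replicate 1 (up to 0.12), and without mock replicate 3, 9 genes rose and 9 fell. Hsp90b1, Hspd1, Dnajb9 and Pdia4 were called lower. Hsp90b1 was not called without mock replicate 2 or any stimulated array (adjusted p up to 0.122) or under other settings (up to 0.227). The heat shock gene Hspa1a rose 55.1-fold and Chac1 9.15-fold.

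The reference genes Gapdh and Actb had log2 fold changes of 0.087 ± 0.21 and 0.058 ± 0.17 (SE) and were not called (adjusted p = 0.771 and 0.821). Their sign turned without mock replicate 3 (-0.072 and -0.023), and with arrays scaled to the median of passing probes both were called higher (0.92 and 0.88).

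**Figure D3:**
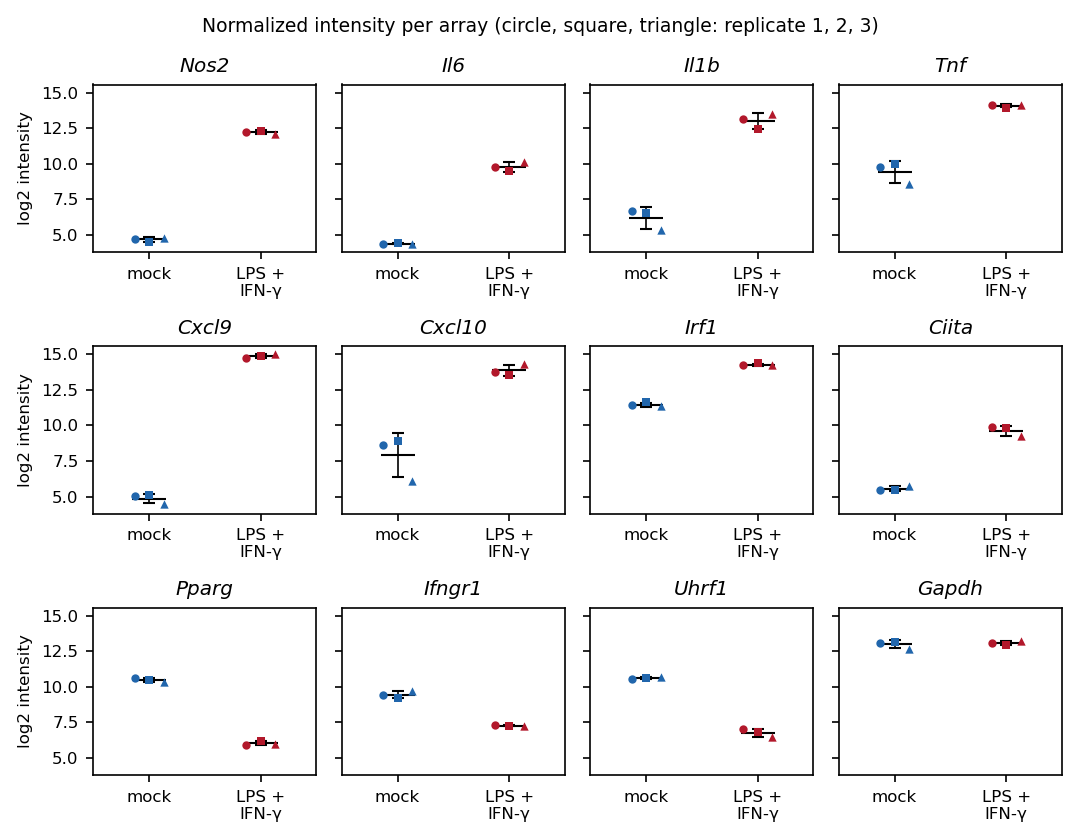
Normalized log2 intensity of 12 genes on each array, mock in blue and LPS with IFN-γ in red, with the mean and SD of the 3 arrays in black and symbols for replicates 1, 2 and 3. Nos2 lies at 4.69 ± 0.15 in mock and 12.22 ± 0.14 in stimulated cells, and mock replicate 3 lies below the other mock arrays for Cxcl10, Il1b and Tnf.

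Markers of other cell types were mostly below background. Of 10 T cell markers on the arrays 3 passed the filter, of which Lck rose, Cd8b1 fell by 2.11 on the log2 scale and Il7r (-0.82) was not called. Of 8 B cell markers 3 passed and Igh-6 fell by 2.02 on the log2 scale. Of 11 neutrophil markers 6 passed, Lcn2, detected on 2 mock arrays, rose by a log2 fold change of 4.58 and Ltf fell, at least 1.23-fold, and mock replicate 3 deviated by a median of -1.47 for this list. Of 9 dendritic cell markers 3 passed and rose, Clec9a at least 2.05-fold and Dpp4 at least 2.00-fold, and Ccr7, detected on 1 mock array, by a log2 fold change of 1.48. Of 8 mast cell and basophil markers 2 passed, and Kit was at least 5.23-fold lower. A single marker passed in each of the stromal, erythroid, natural killer and endothelial lists (Acta2, Hbb-b1, Prf1 and Pecam1), and among these Pecam1 was called, at least 1.99-fold higher.

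Of the 24 lists 16 passed the camera threshold, 14 of them upward and 2 downward. With an estimated correlation 4 passed, those of costimulatory molecules (adjusted p = 0.0391 with an estimated correlation), the NF-kB pathway (0.0273), inflammasome and cell death (0.0413) and the cell cycle (0.0273). On leaving out any mock array, or stimulated replicate 1 or 2, 0 lists passed that test (lowest adjusted p = 0.109, 0.0705 and 0.0999 without mock replicate 1, 2 and 3, and 0.0785 and 0.0769 without stimulated replicate 1 and 2). Without stimulated replicate 3, 2 passed, the NF-kB pathway and the cell cycle. With the replicate number as a block 0 passed (lowest 0.210), and with detection on all 6 arrays only the NF-kB pathway did (0.0350). The NF-kB list had an estimated correlation of -0.0123, below the preset 0.01. Its unadjusted camera p still went from 4.02e-13 to 0.00129, so the weaker p-values do not stem from gene correlation alone. Fewer arrays or a block also lower the residual degrees of freedom, so the lost lists do not by themselves show dependence on single arrays.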

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

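The alternatives that use normexp without controls, vomeronasal receptor controls, scaling to the median of passing probes or removal of the probe start trend were chosen after seeing the data. No gene called with the main settings was called in the opposite direction under any alternative (0 genes in each). Changed genes went from 4279 to 7557 with array weights (3066 higher and 4491 lower) and to 2808 with detection on all 6 arrays (1499 lower, 1024 of them at least 2-fold), where fewer genes were tested (8630). Scaling to the median of all probes gave 1112 higher and 4814 lower, 3498 of the latter at least 2-fold, and the cause was not tested. Normexp without controls gave 1062 at least 2-fold lower, against 1655 with the main settings. It also used an offset of 50 in place of 16. That offset with the stand-in controls gave 1138, so the drop cannot be put down to the missing controls. Leaving out 1 array gave 2648 to 6159 changed genes, 1082 to 2749 higher and 1400 to 3410 lower, the highest of each without mock replicate 3, of 9974 to 10769 tested. At least 2-fold changed were then 2333 to 2590 (957 to 1314 higher, 1212 to 1425 lower), and 13 to 19 lists passed. With an estimated correlation 4 of 16 lists passed, 0 to 2 with 1 array left out, 1 with detection on all 6 arrays, 8 with no filter and 2 or 3 with the scalings. With scaling to the median of all probes the members changed. There the NF-kB (camera adjusted p = 0.0505 with an estimated correlation), inflammasome (0.0552) and cell cycle (0.0703) lists missed. The costimulatory (0.0487), inflammatory cytokine (0.0440) and nitric oxide enzyme (0.0440) lists passed. The test fry, which does not compare with other genes, called also the attractant receptor, alternative activation, lysosome, identity and unfolded protein lists.

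Most reversals were in small changes that were not called, with Rpl3, called lower, the exception among genes. Gapdh and Actb turned to -0.092 and -0.021 with array weights and -0.088 and -0.089 with the probe start trend removed, and ranged from -0.072 to 0.18 and -0.023 to 0.13 with 1 array left out. With scaling to the median of passing probes the medians of the TCA cycle (0.26), LXR (0.20), lysosome (0.47), macrophage identity (0.47), ribosomal (0.58) and unfolded protein (0.27) lists turned positive, as did Rpl3 (0.38). With scaling to the median of all probes the attractant receptor list turned to -0.36, and with no filter the alternative activation list passed (-0.32). The unfolded protein list was 0.017 with no filter, with a detection threshold of 0.05 and with vomeronasal receptor controls, and -0.013 to 0.12 with 1 array left out. The TCA cycle list ranged from -0.32 to 0.061 and the ribosomal list from -0.59 to 0.078 with 1 array left out. Apart from the scalings, whose construction shifts all genes, the cause was not tested.

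Of 154 called genes that the rule named, 134 stayed on the same side of the threshold wherever they were measured. The other 20 kept their direction, Rpl3 excepted, and lost the call in at least 1 alternative, among them Alox5ap, Bcl2l11, Ccne1, Clspn, Cxcl14, Cycs, Gusb, H2-Ab1, Hsp90b1, Mrc1, Mylip, Nr1h3, Pdk1, Psmb9, Rpl3, Rpl4, Spi1, Tgfb1 and Tlr4. The plain equal-variance test lost 14 of them and no filter lost 11. The rule took mostly large or bright called changes, so the share of 134 does not measure how stable calls are in general. Of 156 named genes measured, 143 were tested without a mock array, 140 without a stimulated array and 116 with detection on all 6 arrays. Genes not tested there could not lose a call. With the replicate number as a block 3909 genes changed, 16 lists passed (0 with an estimated correlation), and the calls of Rpl3 and Tgfb1 were lost. Deviations of same-numbered arrays from their group means correlated at 0.157, 0.0883 and 0.135, and each array correlated best with its own number in the other group. Mock replicate 3 dominated the mock deviations (r = -0.931 and -0.932 with mock replicates 1 and 2). These values therefore do not settle whether same-numbered samples were paired, and no label says so. The slide as a block was not run, since no label ties a slide to a sample, and the second deposited table was not run as a source for the same reason; the value table planned as an alternative was itself the main source. Signal over background limits the dim genes, for which only bounds on the fold could be given.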

Other observations

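Biological process terms from the deposited probe annotation, tested with camera after the data were seen, added groups beyond the lists, with which some share genes. Of 127 terms with 15 to 200 measured genes, 7 ranked higher and 5 lower in stimulated cells, and 0 passed with an estimated correlation. DNA repair genes fell in 41 of 92 and rose in 7 (median log2 fold change -0.48, camera adjusted p = 0.0208; adjusted p = 0.358 with an estimated correlation). Genes of the regulation of apoptosis rose in 17 of 42 and fell in 7 (median 0.60, camera adjusted p = 0.0348; adjusted p = 0.388 with an estimated correlation). Protein biosynthesis genes fell in 28 of 149 and rose in 9 (median -0.19, camera adjusted p = 0.587), and the term passed without mock replicate 3 (camera adjusted p = 0.0110; adjusted p = 0.474 with an estimated correlation).

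In the tests that follow, those of transcript length and of stimulated cells for mock replicate 3, of its T cell markers, and of mock replicate 3 alone for the number of detected probes were chosen only after the result was seen. The design gives no biological explanation for mock replicate 3, and beyond cells of another type or stimulated cells added to the culture none was tested.

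The deviation of mock replicate 3 from mock replicates 1 and 2 rose with the probe's start in its transcript (Spearman rho = 0.644 across 9051 genes, which are not independent replicates), from a median of -1.13 for starts up to base 500 to 0.63 beyond base 4000, and after removal of this trend, 43.4% of its variance, it fell with the probe's GC content (rho = -0.235), so that a technical difference in RNA or labelling may account for part of it; the test had required the rho to exceed 2 times that of every other array, which mock replicates 1 and 2 cannot meet because mock replicate 3 is among their mates (up to 0.637 in size), and the stimulated arrays and mock replicate 1 against 2 reached 0.106. Cells of another type had been expected to lift a marker list by over 1 log2 unit, and the T cell list did so, with a median of 1.02, so the criterion set beforehand for that explanation was met. For added T cells the tables argue against it all the same: 2 of 10 T cell markers were detected on mock replicate 3 (Cd8b1 and Il7r, both also detected on mock replicates 1 and 2), Cd3d, Cd3e and Cd3g were at background there (unnormalized intensities of 44.0, 41.1 and 36.5), and the next highest list with at least 3 measured markers had a median of 0.039. Whether mock replicate 3 held fewer cells of another type was not tested, and the neutrophil list had a median of -1.47 there. Stimulated cells in the culture are argued against by a median deviation of -1.06 for the 10 genes with the largest rise against mock replicates 1 and 2, among those detected on these and on all stimulated arrays, while Cxcl9, Nos2 and Il27 were above background on no mock array, and a technical difference stays open.

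Interferon-stimulated genes were lower in mock replicate 3 than in the other mock arrays. Their median deviation was -0.57 over 30 genes, while the central 95% of 10000 random lists matched on probe start and mean level ran from -0.13 to 0.47, and 0% of the random lists lay as low. By this test the trend with transcript length alone did not account for this part. The random lists were not matched on GC content, so a technical share stays open. Their genes were drawn independently, while those of this list were correlated (estimated correlation 0.306), so their range may be too narrow. A difference in basal interferon response between the mock cultures is a hypothesis that was not tested.

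Fewer probes were above background after stimulation. The gap did not rest on mock replicate 3: the lower of mock replicates 1 and 2 exceeded the highest stimulated array by 1518 probes. Transcript length was tested on normalized fold changes of the probes that represent the tested genes, not on the probes that lost detection. It therefore cannot exclude a share of transcript length in the gap. Without mock replicate 3 the fold change showed almost no trend with the probe's start (rho = -0.0182). With all arrays, as in the main comparison, that rho was -0.237. The median log2 fold change then fell from 0.18 for the earliest probe starts to -0.43 for the latest. The fold changes reported with all arrays therefore carry this trend. Dimmer stimulated arrays may account for the gap in detected probes. Without normalization the 56 ribosomal, TCA cycle and respiratory chain genes had a median log2 difference of -0.40 (stimulated minus mock). Without mock replicate 3 this difference was -0.69. A lower level of those genes in stimulated cells would give the same value and stays open.

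The 6 arrays can be split 3 against 3 in 10 ways, so the share of splits with a result as large cannot fall under 0.1, and 1 of the 10, the real one, gave as many in each case. The real split gave 4279 changed genes and the highest other 0, 2931 changed at least 2-fold against 0, and 16 lists past the threshold against 14. Each other split sets 2 arrays of a group with 1 of the other, so it still holds part of the treatment difference and is no reference for unchanged samples.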
